A study of Homo sapiens with 23 samples.

How the data were processed

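The series holds 11 SAGE-Seq libraries and 12 RNA-Seq libraries, all human. In the SAGE-Seq arm, DsRED-labelled breast carcinoma lines and GFP-labelled primary cancer-associated fibroblasts were kept in Matrigel for 17 hours, either apart or together, per the labels' protocols. Separately cultured carcinoma cells were mixed with fibroblasts after release from the gel, so that both arms passed the same bead capture of epithelial cells, and 1 further library came from fibroblasts alone. In the RNA-Seq arm, fibroblasts of different origin and astrocytes were expanded in culture and poly(A) RNA was sequenced.

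The deposited SAGE-Seq table gives whole-number tag counts for 12393 genes, and the submitters' processing notes name CASAVA 1.8.2 and the build hg18. The deposited RNA-Seq table gives read counts for 24051 genes, of which 3558 are at 0 in every library. For that table the submitters' processing notes name CASAVA 1.8.2, FastQC, STAR and HTSeq and the builds GRCh37, hg19 and hg18, without saying which step used which. The matching of tags to genes, the annotation and the strand setting are not given in the sources used here. No filter or normalization of the counts by the authors is recorded in the file headers, and no row was without a gene name. Because the roles of the builds are not given, genes are identified by the symbols in the tables and no coordinates are given. Of the SAGE-Seq symbols, 11790 matched a RefSeq symbol or synonym, and of the RNA-Seq symbols 23320 did. The SAGE-Seq table has no row for ERBB2, KRT14, COL1A1, STAT3 or TFF1, which were not analysed here. Genes of X inactivation and the Y chromosome were left out of all tests, 10 in the SAGE-Seq table and 105 in the RNA-Seq table.

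Library totals, in M (1e6) counts, ranged from 22.5 to 98.8 M counts in the epithelial SAGE-Seq libraries, reached 112 M for the fibroblasts alone, and ranged from 10.3 to 24.5 M in RNA-Seq. Tags and reads carry no molecular identifiers, so intervals and floors cover counting error only. In SAGE-Seq, 6 libraries (MCF10DCIS, MDA-MB-453 and SUM149PT, both cultures) held no gene at 0, whereas the other 5 held between 46 and 135 such genes, 291 genes in all. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per degree of freedom was 498 in SAGE-Seq (20 pairs) and 47.5 in RNA-Seq (15 pairs).

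Counts were tested with edgeR 4.0.16 in R 4.3.3: low counts were removed with filterByExpr, libraries were scaled with TMM, and the quasi-likelihood test was applied with Benjamini-Hochberg adjustment at 0.05. The SAGE-Seq fits used the 10 epithelial libraries with the cell line as a block, since each line supplied 1 separate and 1 co-cultured library. Log2 levels of the same line correlated at 0.908 to 0.971 between the cultures. A fit with 1 co-culture coefficient per sub-type gave the triple-negative, luminal and difference tests. The RNA-Seq fits used all 12 libraries without a block. The labels do not say whether the RNA-Seq replicates are separate donors or separate cultures, so p-values measure the spread between these libraries, which may be technical. The common biological coefficient of variation was 0.193 in the fit over all lines, 0.154 in the fit by sub-type and 0.488 in RNA-Seq.

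Levels are CPM, counts per M counts of the library scaled by TMM, with means and SDs over libraries. Levels in the fibroblasts alone and the fibroblast marker percents use plain library totals, without TMM. Log2 ratios within a line use a pseudocount of 0.5 CPM. Against a group whose libraries are all at 0, a fold is a lower bound computed with a floor of 3 counts over the group. Where a group holds 1 to 3 counts, the ratio has its exact 95% counting interval. Gene lists, 42 in all, were fixed before the data were examined, as were the samples, the tests, the named-gene rule and every alternative except those said to have been chosen later. Of these lists, 29 applied to SAGE-Seq and 40 to RNA-Seq. They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. For each line alone, the median of a list was placed among 10000 random lists matched on mean expression. Fibroblast transcripts in an epithelial library were measured as the summed CPM of 15 fibroblast markers in percent of their sum in the fibroblasts alone, and compared with an exact two-sided sign-flip test.

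The text names, per comparison, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change at an adjusted p under 0.05 and a mean of at least 3 log2 CPM. These also had to have the same sign in every line covered (SAGE-Seq) or no overlap between the groups (RNA-Seq). Where fewer than 10 qualified, it names the 10 genes with the smallest p. It further draws on up to 4 members of each list with the smallest p among those passing and on fixed panels of lineage genes, and names only part of these. Genes that follow common germline variants, clone names, pseudogenes and small RNAs are not named. Alternatives were DESeq2 size factors, no low-count filter, DESeq2 1.42.0, limma-voom, other sets of libraries, other blocks, other gene sets and leaving out each replicate in turn.

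The scripts were tested on simulated counts with 200 changed genes per comparison. For the triple-negative test, edgeR recovered 98% of 4-fold and 64% of 2-fold changes, with 13 false calls of 175, and DESeq2 made 18 of 188. For the luminal test the false calls were 27 of 201 with edgeR and 18 of 187 with DESeq2. For the difference between the sub-types they were 14 of 145 and 13 of 143. For brain metastasis against breast tumor fibroblasts edgeR recovered 47% of 4-fold and 6% of 2-fold changes, with 2 false calls of 55. There DESeq2 made 44 false calls of 148. For breast tumor against normal breast fibroblasts edgeR recovered 34% of 4-fold changes.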

Results

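Expression was profiled in 5 breast carcinoma lines cultured with or without cancer-associated fibroblasts, and in fibroblasts and astrocytes of different origin. The lines were MCF7 and T47D (luminal, estrogen receptor positive), MCF10DCIS and SUM149PT (triple-negative) and MDA-MB-453 (HER2-positive). Each line gave 1 separate and 1 co-cultured SAGE-Seq library, a method that counts short tags per transcript, and 1 library came from fibroblasts alone. The totals were lowest in MCF10DCIS separate, at 22.5 M counts, against 76.0 M in its co-culture. RNA-Seq covered 5 libraries of fibroblasts from brain metastases, 3 from breast tumors, 2 from normal breast and 2 of astrocytes, with 10.3 to 24.5 M counts each.

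Fibroblast transcripts were measured first, because bead capture can carry fibroblast RNA into an epithelial library. Summed over 15 markers, they stood at 0.927% ± 0.795 (SD, n = 5) of the level in fibroblasts alone in the separate libraries and at 0.789% ± 0.529 (SD, n = 5) in co-culture. The difference of -0.138 percentage points (SD 0.367, n = 5) gave p = 0.5 by the exact two-sided sign-flip test, which cannot reach 0.05 with 5 pairs. By this sum only MCF10DCIS was higher in co-culture, at 0.812% against 0.47%. SUM149PT went from 2.28% to 1.60%. The markers did not move as one, so the sum is not a measure of carried-over RNA alone. By library totals, S100A4 stood at 145 CPM in T47D separate and 1.58 CPM in MDA-MB-453 separate. COL1A2, the marker most abundant in fibroblasts alone at 25700 CPM, stood at 37.3 and 325 CPM in these libraries. Leaving out SUM149PT moved the difference to -0.00217 percentage points, and leaving out MCF10DCIS moved it to -0.258. Matrix genes in place of the markers gave a difference of 0.114 percentage points, with the opposite sign. By the median of the 15 markers' own percents, MCF10DCIS, MDA-MB-453 and T47D were higher in co-culture, by 0.665, 0.143 and 0.042 percentage points, and the mean difference was -0.0515 (exact sign-flip p = 0.75).

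**Figure D1:**
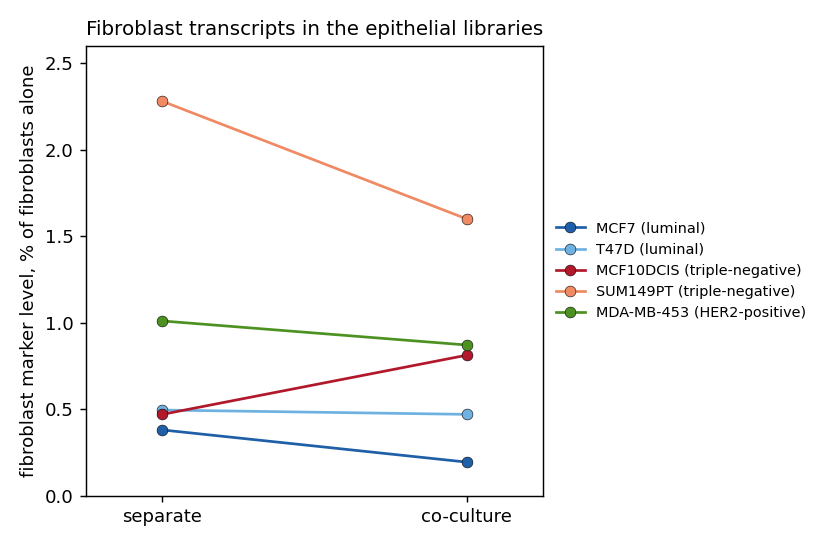
Summed level of 15 fibroblast markers in each epithelial library, in percent of the level in fibroblasts alone (y axis), for separate culture and co-culture (x axis); each line joins the 2 libraries of 1 cell line. Only MCF10DCIS is higher in co-culture, at 0.812% against 0.47%.

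The comparison over all 5 lines asked which transcripts of carcinoma cells change beside fibroblasts whatever the line. SEMA4B, a transmembrane semaphorin, rose by 1.30 on the log2 scale (SE 0.141, adjusted p = 0.0469, edgeR's quasi-likelihood test) and was higher in 5 of 5 lines. Its level went from 35.4 to 72.3 CPM in MCF7, from 42.5 to 87.5 CPM in T47D and from 91.8 to 317 CPM in MCF10DCIS, while the fibroblasts alone held 13.4 CPM. No other gene of the 12205 tested passed, although 851 had an unadjusted p under 0.05 where chance gives 610. Genes next in order did not pass: VWA5A (log2 change 1.86, SE 0.235, adjusted p = 0.0783), the erythroid transcription factor gene NFE2 (1.45, adjusted p = 0.0783), the gasdermin gene GSDMC (2.73, adjusted p = 0.28), VAV3, an activator of Rho GTPases (0.71, adjusted p = 0.342), and F3, which encodes tissue factor (0.66, adjusted p = 0.342). After these came S100A9, a calcium-binding protein of inflamed epithelium (1.89), HSPB1, a small heat shock protein gene (0.78), SLC9A9 (-1.56) and MPZL2 (0.57), each at adjusted p = 0.372. S100A9 had positive log2 ratios in all 5 lines, between 0.71 in MCF7 and 3.03 in T47D. GSDMC stood at no more than 4.68 CPM in any epithelial library. EPCAM, VIM, KRT5, ESR1, PGR, COL1A2 and COL3A1 did not pass, with adjusted p from 0.729 to 0.926. The SEMA4B call was lost with DESeq2 size factors (lowest adjusted p = 0.0527) and without MCF7, T47D, MDA-MB-453 or SUM149PT. DESeq2 called 50 genes, limma-voom 2, and the fit without MCF10DCIS 2.

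Camera called 9 of the 29 lists over the 5 lines. Immediate early and dissociation genes, such as FOS, JUN and EGR1, had 20 of 23 members above 0 and a median log2 change of 0.31 (adjusted p = 1.57e-06, and adjusted p = 0.502 with an estimated correlation). SUM149PT went against it, with 7 of 23 members above 0 and a median log2 ratio of -0.19. JAK-STAT3 targets had 15 of 21 members above 0 (median 0.28, adjusted p = 0.000351, and adjusted p = 0.307 with an estimated correlation). The estrogen response list was lower, with 3 of 18 members above 0 and a median of -0.24 (adjusted p = 0.000351, and adjusted p = 0.232 with an estimated correlation). Interferon response, antigen presentation, ribosomal protein, hypoxia, apoptosis and basal marker lists were also called as higher, with adjusted p from 0.232 to 0.539 with an estimated correlation, and fry called none. In MCF10DCIS the ribosomal protein, hypoxia and antigen presentation medians lay below 0, at -0.162, -0.0449 and -0.0188. In MDA-MB-453 the basal marker median did, at -0.0872, and the other medians of these lists lay above 0. No member of the 9 lists passed over all genes. When adjusted over the list alone, 2 immediate early, 2 JAK-STAT3, 2 antigen presentation, 1 interferon and 1 basal gene were higher, and none of the other 4 lists had a passing member.

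In the triple-negative lines, 211 genes rose and 81 fell in co-culture among 12290 tested. Genes that rose included PLAU, which encodes the protease urokinase (log2 change 1.54, SE 0.256, adjusted p = 0.04), PLXND1, a semaphorin receptor (1.55, SE 0.254, adjusted p = 0.04), SEMA4B (1.48, SE 0.181, adjusted p = 0.04) and L1CAM, a neural adhesion molecule (1.43, SE 0.259, adjusted p = 0.0422). The epithelial adhesion gene EPCAM fell by 1.12 on the log2 scale (SE 0.145, adjusted p = 0.04). The epithelial transcription factor genes GRHL1, OVOL1 and FOXA1 had log2 changes of -1.68, -1.15 and -1.19 (SE 0.274, 0.177 and 0.238, adjusted p = 0.04, 0.04 and 0.0491). EPCAM went from 205 to 96.0 CPM in MCF10DCIS and from 370 to 167 CPM in SUM149PT. DHRS3, a retinaldehyde reductase gene, fell by 2.15 and CLU, which encodes clusterin, by 1.22 (adjusted p = 0.04 each). The 10 largest increases under the naming rule also held FAM46C, CHST10, ZNF34, UCN and NOL7, with log2 changes from 1.34 to 1.75. The rule's mean level covers all lines, and FAM46C stood at 84.7 and 58.3 CPM in MCF7. In the lines tested it went only from 0.229 to 0.658 CPM (MCF10DCIS) and from 0.424 to 1.53 CPM (SUM149PT). The 10 largest decreases also held ABAT, a GABA transaminase gene, the estrogen sulfotransferase gene SULT1E1, OTUB2, AGPAT9, EPB41L4A and RBPMS, with log2 changes from -1.55 to -1.20. Of 23 epithelial adhesion and identity genes 2 fell and none rose, and 2 and 1 did when adjusted over the list alone, and the list was not called (camera adjusted p = 0.616). All adjusted p of the calls lay between 0.04 and 0.05, and 2963 genes had an unadjusted p under 0.05 where chance gives 614.

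Among fixed lists, basal and myoepithelial markers had 6 of 6 tested members above 0 and a median log2 change of 0.81 (camera adjusted p = 0.00597, and adjusted p = 0.949 with an estimated correlation). The fixed list held 16 genes, and the others were not tested in SAGE-Seq. ITGA6, an integrin of the basal surface, rose by 1.19 (SE 0.178, adjusted p = 0.04), and 2 of the 6 passed when adjusted over the list alone. KRT5 had a log2 change of 1.02 and adjusted p = 0.168. Matrix genes went both ways: FMOD (2.78, SE 0.458) and COL4A1 (1.08, SE 0.196) rose and SPARC fell by 0.80, out of 38, while 3 higher and 2 lower passed when adjusted over the list alone. FMOD and COL4A1 stood at 130 and 315 CPM in the fibroblasts alone, and the fibroblast marker list had a median log2 ratio of 1.04 in MCF10DCIS and -0.52 in SUM149PT. FMOD itself went only from 0.183 to 3.22 CPM in MCF10DCIS and from 0.403 to 1.63 CPM in SUM149PT. It stood at 57.5 and 43.4 CPM in MDA-MB-453. Of 16 protease genes PLAU rose and PLAT fell (2 and 1 when adjusted over the list alone), and of 28 hypoxia genes CA9, a carbonic anhydrase gene, rose by 1.53 (SE 0.225; 2 when adjusted over the list alone). IFI6 rose by 1.05 as the sole call among 30 interferon genes, and INSIG1 fell by 0.92 as the sole call among 21 sterol and lipid synthesis genes (2 and 1 when adjusted over the list alone). None of these lists was called. Among members of other lists, ID2, a target of TGF-beta and BMP signalling, fell by 2.34 (SE 0.284, adjusted p = 0.04), and BAD, HLA-F, XPC and RPL35 rose, with log2 changes from 0.73 to 0.95. VIM, the mesenchymal filament gene, did not pass (1.43, adjusted p = 0.0713), with 231 to 1140 CPM in MCF10DCIS and 57.7 to 84.6 CPM in SUM149PT. With DESeq2 size factors no gene passed (lowest adjusted p = 0.0507), DESeq2 called 1203 (700 higher and 503 lower) and the triple-negative libraries alone 963. Without MCF10DCIS, SUM149PT being then the sole triple-negative pair, 18 genes were higher and 30 lower, the opposite balance, and 17 of these 48 were among the 292. Without SUM149PT 318 passed, of which 111 were among the 292, while 515 passed without MCF7 and 495 without T47D.

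**Figure D2:**
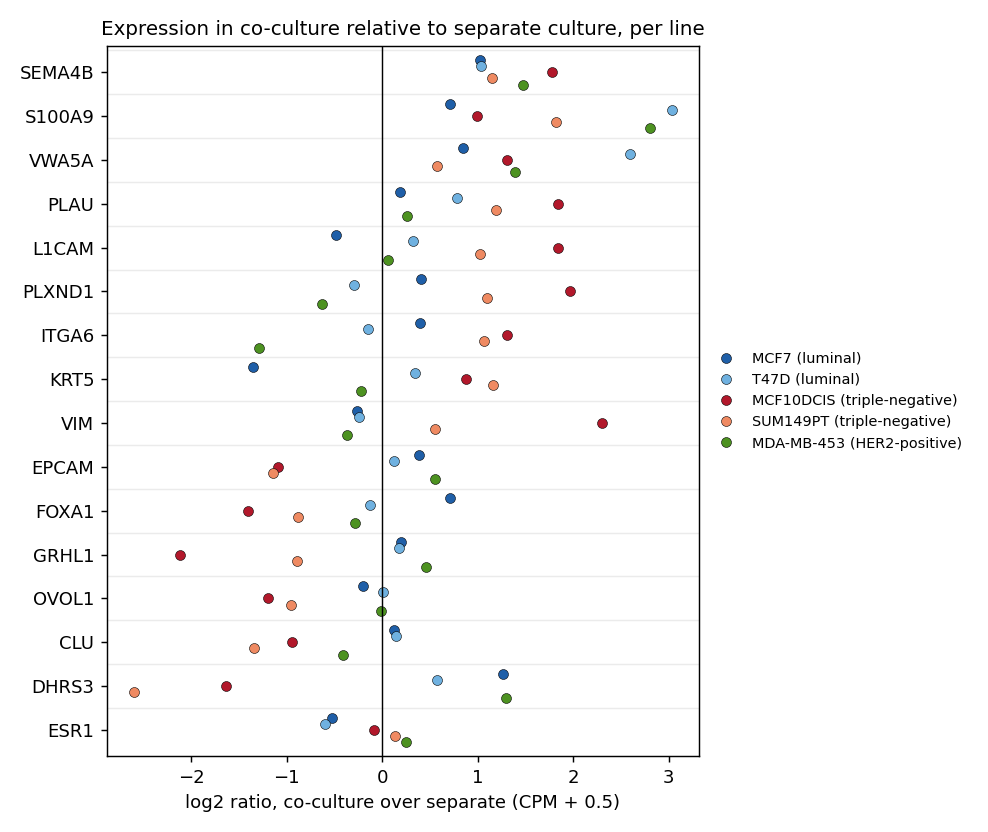
Log2 ratio of co-culture over separate culture (x axis, CPM + 0.5) for 16 genes (y axis), with 1 point per cell line. SEMA4B lies above 0 in 5 of 5 lines, while EPCAM lies at -1.09 in MCF10DCIS and -1.14 in SUM149PT and above 0 in the other 3 lines.

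In the luminal lines no gene passed edgeR's test; 946 had an unadjusted p under 0.05 where chance gives 614, DESeq2 called 67 and limma-voom 1. The smallest p belonged to DOK7, an adaptor of muscle receptor kinase signalling (log2 change -1.47, SE 0.148, adjusted p = 0.0926), and GSDMC (4.23, SE 0.45, adjusted p = 0.0926). GSDMC went only from 0.0722 to 0.588 CPM in MCF7 and from 0.171 to 4.68 CPM in T47D. Next came FGB, an acute-phase fibrinogen gene (1.99), and EGLN3, an oxygen-sensing hydroxylase gene (1.08), each at adjusted p = 0.363, as were SLCO2A1, TNFAIP8, MBNL2, VWA5A, DUSP10 and MYO1B. ESR1 had a log2 change of -0.57 (adjusted p = 0.501), from 45.8 to 31.6 CPM in MCF7 and from 60.2 to 39.5 CPM in T47D. Camera called 13 lists, none with an estimated correlation and none with fry. Immediate early genes had 22 of 23 members above 0 (median 0.48, adjusted p = 2.88e-09, and adjusted p = 0.678 with an estimated correlation), and p53 targets 17 of 18 (0.23, adjusted p = 0.000432, and adjusted p = 0.678 with an estimated correlation); 3 and 1 were higher when adjusted over the list alone. Estrogen response genes had 5 of 18 above 0 (median -0.40, adjusted p = 1.15e-05, and adjusted p = 0.678 with an estimated correlation), of which 5 lower and 1 higher passed when adjusted over the list alone. Cell cycle genes had 3 of 26 above 0 (median -0.18, adjusted p = 0.000432, and adjusted p = 0.678 with an estimated correlation). By line, they had 13 of 26 above 0 in MCF7 (median log2 ratio -0.0069) and 1 of 26 in T47D (-0.287). Immediate early genes had 14 of 23 above 0 in MCF7 (0.212) and 22 of 23 in T47D (0.682). In MCF7 and T47D, estrogen response genes had 5 and 2 of 18 above 0, and p53 targets 12 and 15 of 18. Fits without MCF7, T47D, MCF10DCIS or SUM149PT called 15, 10, 45 and 36 genes, and the luminal libraries alone 6.

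The difference between the sub-types was tested directly, and edgeR called no gene; 2361 had an unadjusted p under 0.05 where chance gives 614, DESeq2 called 560 and limma-voom 0. DHRS3 (-3.12, SE 0.396), FGFR4 (1.67, SE 0.222) and CA9 (2.13, SE 0.308) were among the 10 with the smallest p, as were RECQL4, NTN4, FAM46C, TROAP, VTCN1, ID2 and TMEM80, each at adjusted p = 0.138. EPCAM had -1.38 (SE 0.204, adjusted p = 0.138). Matrix and collagen genes had a median difference of 0.58 (29 of 38 above 0, camera adjusted p = 0.0115, and adjusted p = 0.925 with an estimated correlation) and immediate early genes of -0.48 (3 of 23 above 0, adjusted p = 0.0115, and adjusted p = 0.925 with an estimated correlation). When adjusted over the list alone, 2 matrix genes and 0 immediate early genes passed. Both lists differed within the triple-negative sub-type: the immediate early median was 0.48 in MCF10DCIS and -0.19 in SUM149PT, and the matrix median 0.61 and -0.26. Without SUM149PT 143 genes passed, without MCF10DCIS 17 and without T47D 11.

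Each line alone offers 1 pair of libraries and no test, so its values describe those libraries. In T47D, CHRD was 9.29-fold higher in co-culture, S100A9 8.16-fold, the complement gene CFB 7.53-fold, CEBPD 7.39-fold and the acute-phase gene SERPINA3 6.91-fold, and CXCL12 was 4.01-fold lower. In the HER2-positive MDA-MB-453, S100A8 was 7.47-fold higher, S100A9 6.97-fold, SERPINA3 6.88-fold and the metallothionein gene MT2A 4.23-fold, and OSGIN1 was 3.15-fold lower. MCF7 had 149 genes at least 2-fold lower and 13 higher, with DYNLL1 14.1-fold and EIF2D 10.1-fold lower, and the interferon-induced IFIT2 2.83-fold and IFIT3 2.10-fold higher. DYNLL1 in MCF7 stood at 315 CPM in separate culture, near the 327 to 518 CPM of the MCF10DCIS, MDA-MB-453 and SUM149PT libraries, and at 21.8 CPM in co-culture. STARD10, 4.96-fold lower, stood at 1200 CPM in separate culture, above the 22.9 to 843 CPM of those libraries, and at 242 CPM in co-culture. MCF10DCIS had the anchoring collagen gene COL7A1 7.03-fold, SERPINE1 5.85-fold and VIM 4.93-fold higher, and CYP1A1 13.2-fold, ELF3 7.69-fold and KRT8 4.45-fold lower. SERPINE1 and VIM stood at 11200 and 8800 CPM in the fibroblasts alone. In SUM149PT, SERPINE1 was 3.74-fold lower, ID3 4.13-fold lower and NNMT 2.98-fold higher. The JAK-STAT3 median lay at percentile 100 of random lists in T47D, 99.2 in MCF10DCIS, 82.9 in MCF7, 77.0 in MDA-MB-453 and 37.9 in SUM149PT. Estrogen response lay at percentile 0 in T47D, 0.29 in MCF7, 0.01 in MDA-MB-453, 12.8 in MCF10DCIS and 28.6 in SUM149PT. Cell cycle genes lay at 0 in T47D and between 31.6 and 73.4 in the other 4 lines.

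**Figure D3:**
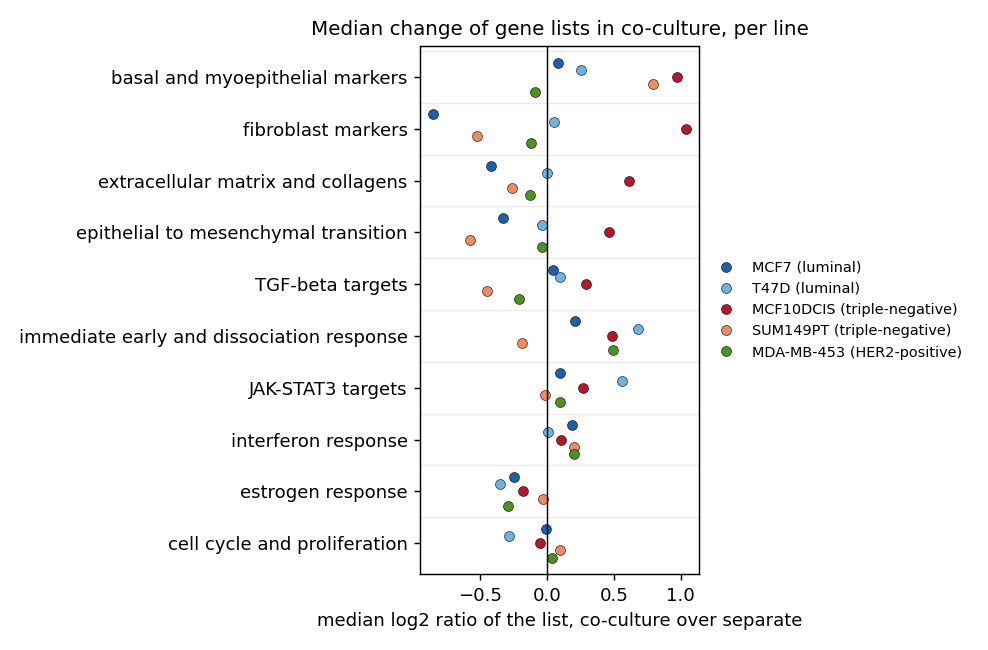
Median log2 ratio of co-culture over separate culture (x axis) for 10 gene lists (y axis), with 1 point per cell line. Basal markers lie at 0.97 in MCF10DCIS and 0.79 in SUM149PT, and the fibroblast marker list lies at 1.04 in MCF10DCIS and -0.52 in SUM149PT.

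Fibroblasts from brain metastases were set against those from breast tumors to ask how the site marks them. Of 15462 genes tested, 264 were higher and 343 lower in brain metastasis fibroblasts. HOX genes, which record position along the body axis, were lower: 24 of 29 tested HOX genes fell and none rose. HOXC8 had 0.0892 CPM ± 0.112 (SD, n = 5) against 66.9 CPM ± 3.46 (SD, n = 3), a log2 change of -9.43 (SE 0.625, adjusted p = 0.000227). HOXC10 was at 0 in all 5 libraries and at least 718-fold lower, and HOXD8 at least 450-fold lower. HOXA5 was 1190-fold lower by 1 count (95% counting interval 212 to 47000). TBX5, a limb and heart transcription factor, was at least 572-fold lower and HAND2 was 1010-fold lower (95% counting interval 279 to 8340). ZIC genes, transcription factors of dorsal brain and meninges, were higher: ZIC1 stood at 200 CPM ± 72.3 (SD, n = 5) against 0.268 CPM ± 0.42 (SD, n = 3; log2 change 9.46, SE 1.29, adjusted p = 0.00618), ZIC4 had a log2 change of 8.24 (SE 0.8), ZIC5 was at least 252-fold higher and ZIC2 was 847-fold higher (95% counting interval 290 to 4110). FGFR2 had a log2 change of 8.21 and IGFBP1, an insulin-like growth factor carrier, of 9.81 (adjusted p = 0.0228 and 0.0192). The 10 largest increases under the naming rule also held PPP1R1B, IGFN1, the neurotrophin receptor gene NTRK2 and the somatostatin receptor gene SSTR2, with adjusted p from 0.0254 to 0.0389. The 10 largest decreases also held HOXB6, the chemokine receptor gene DARC, CADM3, ALOX15B and MMP3, with adjusted p from 0.00179 to 0.0217.

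**Figure D4:**
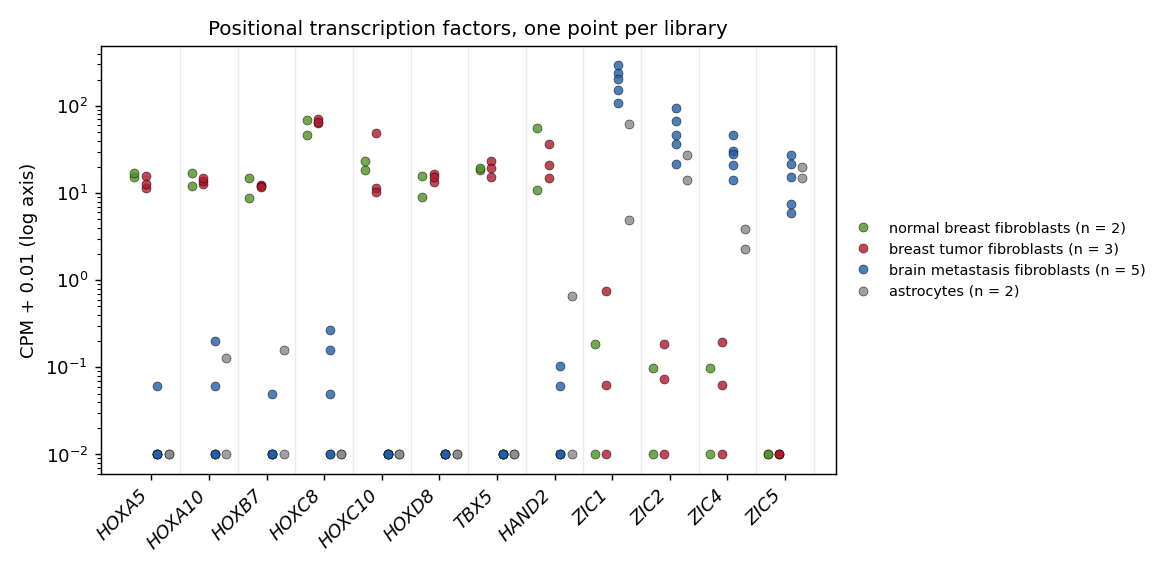
CPM plus 0.01 (y axis, log scale) of 12 positional transcription factor genes (x axis), with 1 point per library for normal breast fibroblasts (n = 2), breast tumor fibroblasts (n = 3), brain metastasis fibroblasts (n = 5) and astrocytes (n = 2). HOXC10, HOXD8 and TBX5 are at 0 in the 5 brain metastasis libraries, and ZIC5 is at 0 in the 5 breast libraries.

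The 4 HOX lists were the ones called with an estimated correlation: HOXA with 10 of 10 members lower (camera adjusted p = 3.42e-46, and adjusted p = 0.00179 with an estimated correlation), HOXB with 4 of 8 (adjusted p = 0.0238 with an estimated correlation), HOXC with 6 of 7 (0.00266) and HOXD with 4 of 4 (0.00788). Adjusted over the list alone, 10, 8, 7 and 4 were lower. Of 32 anterior and cranial patterning factors 6 rose and 2 fell, and 11 and 6 when adjusted over the list alone (camera adjusted p = 0.00035, and adjusted p = 0.107 with an estimated correlation). Of 17 limb and trunk patterning factors none rose and 4 fell, and 1 and 6 when adjusted over the list alone (camera adjusted p = 9.16e-06, and adjusted p = 0.0889 with an estimated correlation). Of 16 markers of meningeal fibroblasts 4 rose and none fell, and 7 and 0 when adjusted over the list alone, among them FOXC1 (5.06, SE 1.06) and PTGDS (6.24, SE 1.46), with adjusted p = 0.0889 for the list with an estimated correlation. General fibroblast markers were called lower (3 of 18, and 4 when adjusted over the list alone; camera adjusted p = 4.42e-06, and adjusted p = 0.302 with an estimated correlation), with THY1 at -3.92 (SE 0.386) and S100A4 at -3.85 (SE 0.695), whereas COL1A1 (-0.63, adjusted p = 0.667), PDGFRA (adjusted p = 0.324), PDGFRB (adjusted p = 0.318), ACTA2 (adjusted p = 0.239) and FAP (adjusted p = 0.18) did not pass. Mural cell markers had 1 of 13 higher, and 4 when adjusted over the list alone (camera adjusted p = 0.0565), with means of 4.82, 5.10, 5.34, 6.34 and 6.49 log2 CPM in the brain metastasis libraries and 4.38 to 4.88 in the breast tumor libraries. Endothelial markers had 0 of 11 higher, and 2 when adjusted over the list alone (camera adjusted p = 0.0765). Of 46 matrix genes 1 rose and 2 fell (2 and 3 when adjusted over the list alone), with COL7A1 at 3.44 (SE 0.692) and TNC, which encodes tenascin-C, at -4.26 (SE 0.904). Hypoxia genes had 1 of 32 above 0 (median -0.73, camera adjusted p = 2.17e-06, and adjusted p = 0.551 with an estimated correlation), and 2 fell, also when adjusted over the list alone, among them CA9 with a log2 change of -8.06 (SE 0.866). All 47 ribosomal protein genes lay below 0 (median -0.65, adjusted p = 0.492 with an estimated correlation), none passed over all genes and 36 did when adjusted over the list alone. EPCAM, PTPRC and PECAM1 did not pass the low-count filter.

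The balance of higher and lower genes depended on the test and the libraries. DESeq2 called 2283 genes, of which 603 were among the 607 of edgeR, and more were higher than lower, 1252 against 1031. Limma-voom called 155 higher and 357 lower. Leaving out brain metastasis library 1 or 4 left 251 calls (91 higher) and 197 (66 higher), and leaving out breast tumor library 1, 2 or 3 left 175 (47 higher), 139 (29 higher) and 150 (29 higher).

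Fibroblasts from breast tumors did not differ from those of normal breast in any single gene by edgeR's test; 546 genes had an unadjusted p under 0.05 where chance gives 773, DESeq2 called 4 and limma-voom 0. The smallest p belonged to MAP1A, a microtubule-associated protein gene, at 224 CPM ± 12.7 (SD, n = 3) against 95.7 CPM ± 20.5 (SD, n = 2), with a log2 change of 1.23 (SE 0.23, adjusted p = 1). ATF6B, BRIX1, FKBP8, SLC39A8, ASTN1, HDAC11, MXD4, HDGFRP3 and MINK1 came next, each at adjusted p = 1. COL1A1 had a log2 change of 0.88, FAP of 0.23 and ACTA2 of 0.66 (adjusted p = 1 each). Camera called 4 lists. Inflammatory fibroblast genes, cytokines and chemokines for the most part, had 1 of 25 members above 0 (median -1.74, adjusted p = 1.21e-08, and adjusted p = 0.079 with an estimated correlation), and NF-kB and chemokine genes 3 of 30 (adjusted p = 2.93e-10, and adjusted p = 0.297 with an estimated correlation). Cell cycle genes had 1 of 38 above 0 and hypoxia genes 27 of 32 (adjusted p = 0.922 each with an estimated correlation). None of their members passed over all genes or when adjusted over the list alone, and fry called no list.

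Against normal breast fibroblasts, 66 genes were higher and 178 lower in brain metastasis fibroblasts. IGFBP1 was at least 1900-fold higher and ZIC5 at least 131-fold higher, and ZIC1 was 2420-fold higher (95% counting interval 670 to 20000). TBX5 was at least 564-fold lower, HOXC10 at least 623-fold lower, and HOXC8 had a log2 change of -9.21 (SE 0.638, adjusted p = 0.000333). The 10 largest increases under the naming rule also held ZIC2, ZIC4, UNC13A, SLC16A6, the glycine decarboxylase gene GLDC, the retinol receptor gene STRA6 and FAM49A, with adjusted p from 0.00334 to 0.0385. The 10 largest decreases also held HAND2, HOXB6, IL13RA2, GREM2 and TMEM155, with adjusted p from 0.00286 to 0.0103. Camera called 21 of 40 lists, and 5 were called with an estimated correlation. The 4 HOX lists had adjusted p of 0.0021, 0.0234, 0.00213 and 0.0141 with an estimated correlation. Inflammatory fibroblast genes were lower, with 5 of 25 above 0 (median -2.13, camera adjusted p = 1.98e-08, and adjusted p = 0.018 with an estimated correlation); 3 passed over all genes, 7 when adjusted over the list alone, and IL33, an alarmin, had a log2 change of -7.69 (SE 0.586, adjusted p = 0.000333). SOD2, a mitochondrial superoxide dismutase induced by NF-kB, had -2.69 (SE 0.326), and MMP3, a stromelysin, -10.38 (SE 1.56). Endothelial markers had 11 of 11 members above 0 and mural cell markers 9 of 13 (camera adjusted p = 0.00908 and 0.0166, and adjusted p = 0.126 and 0.351 with an estimated correlation). None of them passed over all genes, and 0 and 2 were higher when adjusted over the list alone. The excess of lower genes was not kept by DESeq2, which called 1366 genes, 694 higher and 672 lower, whereas limma-voom called 39 higher and 163 lower. The 2 groups alone gave 111 (20 higher). Leaving out brain metastasis library 1 or 4 left 122 calls (27 higher) and 94 (18 higher), and normal breast library 1 or 2 left 136 (17 higher) and 98 (17 higher).

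Astrocytes differed from brain metastasis fibroblasts in 1574 genes that were higher and 772 that were lower. GFAP, the astrocyte filament gene, had a log2 change of 9.16 (SE 1.92, adjusted p = 0.0112), SOX2 of 9.01, S100B of 8.95, the forebrain factor FOXG1 of 9.47 and the progenitor antigen gene PROM1 of 9.63 (SE 1.01, adjusted p = 0.000639). The 10 largest increases under the naming rule also held ADD2, MLC1, LIX1, KLHDC8A, DLK1, LRRN1, TGFA and CHL1, with adjusted p from 0.00101 to 0.0153. Of 17 astrocyte markers 11 rose (camera adjusted p = 0.000259, and adjusted p = 0.475 with an estimated correlation), and 11 rose and 1 fell when adjusted over the list alone. Of 10 neuron markers 3 rose, SYT1, GAD1 and NEFL (3.84, 8.14 and 5.77), and 4 when adjusted over the list alone (camera adjusted p = 0.0128, and adjusted p = 0.475 with an estimated correlation). Their mean was 1.88 and 4.27 log2 CPM in astrocyte libraries 1 and 2, against 0.853 to 1.40 in the brain metastasis libraries. Of 18 fibroblast markers 8 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 6.24e-05, and adjusted p = 0.475 with an estimated correlation): COL3A1 had 30.0 CPM ± 25.9 (SD, n = 2) against 8290 CPM ± 4762 (SD, n = 5; log2 change -8.11, SE 1.17, adjusted p = 0.0022), DCN, which encodes decorin, -5.50 (SE 0.921) and PDGFRB -3.27 (SE 0.795). SIX1, a craniofacial homeobox gene, had -8.20 (SE 0.952). C7 was 8200-fold lower by 1 count (95% counting interval 1470 to 324000). The 10 largest decreases also held IGFN1, IGFBP1, SIX2, WNT16, TMEM30B, DKK2, SLC7A2, EBF2 and CLEC3B, with adjusted p from 0.00599 to 0.0441. Of 46 matrix genes 10 were lower and 2 higher (adjusted p = 0.545 with an estimated correlation), and 13 and 2 when adjusted over the list alone; TNC was higher by 5.94. The HOX lists were not called (camera adjusted p from 0.0622 to 0.825). COL1A1, PDGFRA, ACTA2 and FAP did not pass (adjusted p = 0.486, 0.781, 0.249 and 0.266). The 2 astrocyte libraries stood apart: GFAP was 994 and 16460 CPM, COL1A1 14270 and 667 CPM, and FN1 25470 and 264 CPM. Without astrocyte library 2, 751 genes passed (606 higher) and without astrocyte library 1, 2399 (1586 higher), of which 653 and 1586 were among the 2346; DESeq2 called 3738 (2146 higher).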

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

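The test of 9 marker genes in CPM was chosen only after the same genes on a log2 scale had been seen to set no library apart. On the scales used first, 0 of 62 groups of libraries held a library far from the others, where chance gives about 1 in 20, or 3.1. In CPM, the unit of the report, 2 of the 9 genes did, where chance gives 0.4, and a linear scale favours such gaps in skewed levels.

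ACTA2 stood at 1450 CPM in brain metastasis library 4, against 446 CPM in the next and 65.2 CPM in the lowest. GFAP stood at 69.2 CPM in brain metastasis library 5, against 4.55 CPM in the next. The astrocyte libraries held 994 and 16460 CPM of GFAP.

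Triple-negative and luminal lines differed in the co-culture change of 2 lists by a test of the difference itself. Matrix and collagen genes had a median difference of 0.58 and immediate early genes of -0.48 on the log2 scale, with camera adjusted p = 0.0115 each. With an estimated correlation the adjusted p was 0.925 for both. Neither difference ran the same way within the triple-negative sub-type: the matrix median log2 ratio was 0.61 in MCF10DCIS and -0.26 in SUM149PT, and the immediate early median 0.48 and -0.19.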

How the results depend on the processing

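Leaving out the 94 genes that separate the libraries by their pattern of zeros was chosen only after the data were seen. Of 128 alternatives, 64 were counted as kept, 61 moved further and 3 reversed. A count was kept within 1.5 times the reported value, including a 0 that stayed 0. The fibroblast transcript difference was counted as kept by its sign alone. Its values of -0.258, -0.0515 and -0.00217 lay more than 1.5 times away from -0.138. The cause of a change was not tested unless fewer libraries or genes show it. With DESeq2 size factors the counts over all lines and in triple-negative lines were 0 and 0. DESeq2 called 50 genes over all lines, 1203 in triple-negative lines, 67 in luminal lines, 560 for their difference, 2283 for brain metastasis against breast tumor, 4 for breast tumor against normal, 1366 for brain metastasis against normal and 3738 for astrocytes. Limma-voom called 2 genes over all lines and 1 in luminal lines. Over all lines, the fit called 0 without the cell line block, 2 with the fibroblast marker level as a covariate and 3 without the 1815 genes highest in the fibroblast library. Only libraries of the sub-types compared gave 963 (triple-negative) and 6 (luminal) genes, and only the 2 groups gave 111 for brain metastasis against normal. Leaving out the 94 genes gave 413 for the triple-negative lines, within 1.5 times.

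Leaving out each replicate in turn, where the pair of libraries of a line counts as 1, gave 0 to 2 genes over all lines, 48 to 515 in triple-negative lines, 0 to 45 in luminal lines and 0 to 143 for their difference. It gave 139 to 863 for brain metastasis against breast tumor, 94 to 283 for brain metastasis against normal and 751 to 2399 for astrocytes. Lone libraries in such fits are assumed to vary like the other groups. Without astrocyte replicate 1, DUSP2 went to -0.33 and IRX1, with 1 count in the brain metastasis libraries, to -1.27 as fitted. Replicate numbers in RNA-Seq did not pair the samples across all groups. Correlations of same-numbered deviations were -0.16, -0.00694 and -0.0911 between brain metastasis and breast tumor, and 0.00501 and 0.399 between brain metastasis and normal. They were 0.0851 and -0.185 between breast tumor and normal, and -0.116 and 0.0101 between astrocytes and brain metastasis. The best match had the same number for both numbers of brain metastasis against normal and for number 1 of breast tumor against normal. In no other case did it. The replicate block gave 10, 8 and 450 genes for brain metastasis against breast tumor, against normal, and astrocytes, and 0 for breast tumor against normal.

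With an estimated correlation the lists called were 0 over all lines, 0 luminal, 0 triple-negative, 0 for their difference, 4 for brain metastasis against breast tumor, 5 against normal, 0 for breast tumor against normal and 0 for astrocytes; fry gave 0, 0, 0, 0, 11, 12, 0 and 7. The fibroblast transcript difference of -0.138 percentage points reversed to 0.114 with matrix genes. It otherwise ranged from -0.258 (without MCF10DCIS) to -0.00217 (without SUM149PT). At the depth and spread of the RNA-Seq libraries, edgeR recovered at most 6% of 2-fold changes in simulated counts, and what limits it was not tested.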

Other observations

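The tests of depth by thinning and of shared handling for the MCF10DCIS and SUM149PT correlation, and of RNA from other lines in MCF7, were chosen only after the result was seen.

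Of 45 growth factor ligands and receptors, 2 were higher and 3 lower in brain metastasis fibroblasts, 5 and 3 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.934). They had more KITLG, the ligand of KIT (log2 change 1.23 against breast tumor fibroblasts, SE 0.258, adjusted p = 0.0328, edgeR), and less FGFR1 (-1.17, SE 0.188, adjusted p = 0.0116) and GAS6, a ligand of TAM receptors (-3.90, SE 0.88, adjusted p = 0.0402). GJA1, the connexin 43 gene, was higher (1.73, SE 0.235, adjusted p = 0.0061), and RGS5, a gene of pericytes, had 318 CPM ± 408 (SD, n = 5) against 3.95 CPM ± 0.891 (SD, n = 3). CTSB, a lysosomal protease gene, had -1.97 (SE 0.345) and CD68, a lysosomal membrane protein gene, -1.77 (SE 0.246).

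MCF10DCIS and SUM149PT, the triple-negative lines, shared a direction across genes: over 8837 genes their log2 ratios correlated at r = 0.589 (rho = 0.639), against r between -0.231 and 0.292 for the other 9 pairs of lines; genes are not independent replicates. Once the 10 epithelial libraries were thinned to 22.5 M counts each, r was 0.578. The correlated genes had a mean of at least 5 CPM, where thinning could hardly lower r, so it decides little on depth. The co-culture total was 3.38 times the separate total in MCF10DCIS and 0.702 times in SUM149PT. Without the genes highest in the fibroblast library r was 0.63 over 7788 genes, above the bound of 0.4 set beforehand. The larger r of MDA-MB-453, from the same 6 libraries without zeros, with these lines was -0.0807. This cannot decide on shared handling of the 6, since handling common to both cultures of a line cancels in its ratio. Shared handling, also a batch of these 4 libraries alone, stays open and untested. A response shared by the triple-negative sub-type may be a candidate explanation, as a hypothesis that was not tested.

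MCF7 had 149 genes at least 2-fold lower in co-culture and 13 higher. RNA of other lines in its separate library argues poorly for this: by their median, abundant genes of those lines reached at most 0.0037 of the share needed. Processing of the MCF7 separate library like the 6 libraries without zeros may account for part of it. A set of 83 genes, chosen without MCF7, had a median MCF7 log2 ratio of -0.61 (quartiles -1.29 and -0.28). Their T47D median of 0.10 is no control, since the choice required both T47D libraries to be low against those 6. Of the 149 genes, 25 belong to the wider set of 94. By the zeros themselves MCF7 separate was unlike those 6, with 46 genes at 0 against 47 in MCF7 co-culture. This cannot decide on its processing, since a table limited to genes counted in those 6 would show such zeros whatever the processing. Of 3 lower genes looked at singly, DYNLL1 (315 CPM in MCF7 separate) and SDR39U1 (119 CPM) lay far above T47D (at most 16.4 and 8.5 CPM) and near or within those 6 (327 to 518 and 44.4 to 223 CPM), whereas STARD10 (1200 CPM) lay above those 6 (22.9 to 843 CPM), whose lowest is below T47D (at most 71.2 CPM). The remaining genes, and any response of MCF7 to fibroblasts, stay open.

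HOX genes were low in brain metastasis fibroblasts, with 24 of 29 called. Astrocytes among the cells would bring their abundant genes, but the median share of the astrocyte level over 15 such genes was at most 0.0113 in any of the 5 libraries. The share of the 24 genes still called in libraries thinned to 10.2 M counts was 1. This thinning could hardly end calls as wide as HOXC8, at 0.0892 against 66.9 CPM, so it decides little on depth. Totals overlapped between the groups, at 10.3 to 24.5 M counts for brain metastasis and 11.7 to 21.1 M for breast tumor. A different position of origin of these fibroblasts may be a candidate explanation, as a hypothesis that the labels' site of origin names; culture and donor stay open and untested.

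Other splits of the libraries were counted for the comparisons with at least 3 libraries a group. For brain metastasis against breast tumor fibroblasts, 1 of 56 splits gave 607 genes, the real one, which is the smallest share these libraries allow, and the highest other gave 435. A share of 1 in 56 lies under 0.05 but does not exclude chance in how these 8 libraries are grouped. A difference between donors is not excluded either, since the labels do not say which libraries share one. For co-culture over all lines, 8 of 100 splits gave at least the 1 gene of the real one and the highest other gave 8, so chance cannot be excluded. That split keeps both libraries of at least 1 line together, unlike the real one. Among the 12 that part all 5 lines, too few for a share under 0.05, the real one gave 1 gene and the highest other 0.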
